A study of Mus musculus with 12 samples.

How the data were processed

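The data were whole-genome bisulfite sequencing of sorted mouse CD8 T cells, 12 libraries in 8 groups. Per the labels' protocols, sorted cells gave DNA that was converted with a bisulfite kit (Zymo EZ DNA Methylation-Direct), made into libraries with the Epicentre EpiGenome kit and sequenced on an Illumina NovaSeq instrument. Lymph node cells at day 8 were labelled CD8CD90.1CD44. Tumour cells at day 8 were labelled CD8CD90.1PD1+Ly108+Tim3- (TIM3neg below) or CD8CD90.1PD1+Ly108-Tim3+ (TIM3pos), and tumour cells at day 12 only CD8. The titles mark each group M9 or C6M9, which the labels describe as high affinity GP33 and low affinity GP33. M9 and C6M9 are used here as the names of these 2 groups of GP33 antigen.

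Per the submitters' processing notes, the tools were CASAVA 1.7 and BSMAP 2.90 and the genome builds were hg19 and mm10. The positions lie on mouse chromosomes and all CpG coordinates here are given on mm10. Each deposited table has 4 columns with no header: chromosome, position, and a pair of read numbers per cytosine. The first read number was read as a deposited estimated count of effective reads per CpG, since it is not whole at 0.376% to 3.95% of the CpGs of a library. The second was read as the deposited count of methylated reads, which is whole everywhere. The highest coverage of a CpG was 222 to 253 reads per library, so deeply covered CpGs lie near a ceiling whose origin the labels do not state. No step after alignment is stated in the labels, and whether duplicate reads were removed is not known. The 2 day 12 tables list no CpGs on chromosome Y or the mitochondrial genome.

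Each listed position was used as 1 CpG, without merging neighbouring positions. The 19 autosomes were used. A CpG entered a comparison only where every library of the fit had at least 5 reads on it, and a region needed at least 3 such CpGs. Methylated and total reads were summed over the CpGs of a region in each library, and the level is methylated over total reads in percent. Regions were non-overlapping 1 kb tiles, gene ends and gene bodies. Genes came from the RefSeq gene table for GRCm38.p6, the assembly of mm10. That table gives no strand and no exons. The planned promoter (1000 bases upstream to 500 bases downstream of the annotated gene start) could therefore not be placed on the correct side of a gene. In its place, windows of 1000 bases outside and 500 bases inside were laid at both ends of each gene, and the end with the lower mean methylation over all 12 libraries, blind to the groups, was kept. It is called the gene end below. Of 21633 genes it was the end at the lower coordinate for 11001 and the end at the higher coordinate for 10632. The gene body ran from 500 bases inside that end to the other end. A locus was the gene plus 10 kb beyond the chosen end. Exon or intron cannot be told from this table, so tiles are given as within a gene or intergenic.

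Library depth sets the precision of each value. The mean autosomal coverage per CpG ran from 6.08 reads in lymph node C6M9 replicate 2 to 46.5 reads in the M9 day 12 tumour library. In the shallowest library of a fit, the median number of CpG read observations was 42 to 44 per tile, 287 to 301 per gene end and 1177 to 1246 per gene body. Reads without molecular identifiers are not independent molecules, so Wilson intervals given for single libraries cover counting error only.

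Groups were compared with a logistic model of methylated against unmethylated reads across libraries, with an overdispersion per region from the Pearson chi-square. The overdispersion was moderated across regions with squeezeVar of limma 3.58.1 and was not let below 1. A two-sided quasi-likelihood F test on the deviance gave p-values, which were adjusted by Benjamini-Hochberg over all regions of a kind. A region was called at an adjusted p under 0.05 and a difference of group mean levels of at least 10 percentage points. The lymph node comparison used 3 M9 and 3 C6M9 libraries. The 2 tumour comparisons, TIM3pos against TIM3neg and M9 against C6M9, used the 4 day 8 tumour libraries with the other factor as a covariate. The 6 lymph node libraries entered that fit of 10 libraries with their own means and contributed only to the estimate of the spread. TIM3neg tumour cells were compared with lymph node cells over 8 libraries with antigen as a covariate. Groups of 1 library were compared without a test. For these, regions were counted that differed by at least 30 points with at least 20 CpG read observations in each library, beside the same count between lymph node libraries of 1 group. Global levels of the lymph node groups were compared by a two-sided exact permutation test.

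The groups, comparisons, tests, thresholds, gene lists, named-gene rule and most alternatives were fixed before the data were examined. There were 13 gene lists: progenitor and memory, exhaustion and inhibitory receptors, effector and cytotoxic, tissue residency and trafficking, T cell receptor signalling, DNA methylation machinery, T cell identity, CD4 and regulatory T cell markers, B cell markers, myeloid markers, NK cell markers, stromal and melanocytic markers, and imprinted loci. They hold 164 genes, of which 163 matched the gene table. Lists were tested with camera of limma on log2 ratios of methylated to unmethylated reads (pseudocount 1), with a preset correlation of 0.01 and again with an estimated correlation. The number of list members whose locus held a called tile was compared one-sided with 10000 random lists matched on the number of tested tiles. This random-list test was chosen after the data were seen. It did not match on methylation level or on the number of CpGs per tile, and called tiles often differed from tested tiles in both. Its p-values therefore do not separate list membership from the kind of tile. For single libraries, the median difference of a list was placed among 10000 random lists of the same size matched on mean methylation.

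The genes named per tested comparison were chosen by rule. They are at most 15 list members called at an end, a body or a tile of the locus, by the largest difference, the 5 gene ends and 5 tiles each way with the largest difference among those called without overlap of the groups, and 12 key genes reported called or not (Tcf7, Tox, Pdcd1, Havcr2, Ifng, Gzmb, Prf1, Id3, Slamf6, Prdm1, Tbx21 and Bach2). In single-library comparisons they are the key genes and the 5 gene ends each way with the largest difference and at least 50 CpG read observations. Tiles outside genes are given with the nearest gene.

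The test was checked on simulated reads with known differences in 200 regions per comparison, using the depths and spread of each fit. The changed regions had levels between 25% and 75%, while the median tested tile was at 86.6% to 88.8%. Recovery outside 25% to 75% was thus not checked. Of differences of 10, 20 and 30 points, it recovered 5.97%, 61.2% and 97.0% in 60000 simulated tiles of the lymph node comparison, and 47.8%, 98.5% and 97.0% in its 19348 gene bodies. For TIM3pos against TIM3neg it recovered 40.3% at 20 points and 72.7% at 30 points in 60000 tiles, with 0 at 10 points. In its 19264 gene ends it recovered 7.46%, 61.2% and 87.9%. For M9 against C6M9 in the tumour it recovered 7.46%, 32.8% and 78.8% in 60000 tiles, and 10.45%, 65.7% and 83.3% in 19264 gene ends. For TIM3neg tumour against lymph node it recovered 5.97%, 37.3% and 87.9% in 60000 tiles, and 23.9%, 68.7% and 89.4% in 19276 gene ends. Unchanged simulated tiles were called 1 to 6 times per comparison. All libraries of a fit were simulated with the same spread, so these false calls do not check whether tumour libraries spread like lymph node libraries. Camera called only the shifted list, moved by up to 20 points, under both correlation settings. Regions were simulated independently of each other, so this does not check either correlation setting against genes that vary together.

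Alternatives covered the read minimum, the size of the difference, the tile and window sizes, an upper coverage limit, chromosome X, limma on log2 ratios, the overdispersion floor, the spread of the tumour libraries alone, a replicate block and leaving out each replicate. A set of 3 more (limma with read weights, leaving out both lymph node replicate 2 libraries, and leaving out the 2 shallowest libraries) was added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.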

Results

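Methylation was measured at single CpGs in CD8 T cells sorted from lymph node and tumour of mice. The cells met a GP33 antigen of high affinity (M9) or low affinity (C6M9), per the labels. At day 8 there were 3 M9 and 3 C6M9 lymph node libraries. The day 8 tumour gave 4 groups of 1 library each: TIM3neg cells (PD1+ Ly108+ Tim3-) and TIM3pos cells (PD1+ Ly108- Tim3+), each under M9 and C6M9. The day 12 tumour gave 1 library of CD8 cells per antigen. Coordinates below refer to the mm10 genome. PD1 and Tim3 are inhibitory receptors, and Ly108, the product of Slamf6, marks progenitor exhausted T cells. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples. In both day 8 tumour comparisons that spread came mostly from the lymph node libraries, since each tumour group is 1 library. With the spread of the 4 tumour libraries only, 4 of 35 named regions kept their call between TIM3pos and TIM3neg. Between antigens 0 of 33 did.

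Mean autosomal coverage per CpG was 22.0, 16.3 and 14.5 reads in lymph node M9 replicates 1, 2 and 3, and 19.8, 6.08 and 17.3 reads in lymph node C6M9 replicates 1, 2 and 3. In the day 8 tumour it was 17.4 reads for M9 TIM3neg, 20.3 for M9 TIM3pos, 8.83 for C6M9 TIM3neg and 15.3 for C6M9 TIM3pos. The day 12 libraries had 46.5 reads (M9) and 44.6 reads (C6M9). Each library listed 20679819 to 21177031 CpGs.

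Over 12673305 autosomal CpGs covered in all libraries, the lymph node cells were methylated at 77.1% ± 0.230 (SD, n = 3) under M9 and 77.8% ± 0.772 (SD, n = 3) under C6M9. The difference of -0.699 points gave a two-sided exact permutation p of 0.2, where 0.1 is the smallest p that 3 against 3 can give. Tumour cells lay lower. TIM3neg cells were at 74.96% under M9 and 73.7% under C6M9, TIM3pos cells at 73.0% (M9) and 72.9% (C6M9), and day 12 tumour cells at 70.7% (M9) and 71.7% (C6M9). The mean of the TIM3neg libraries lay -3.10 points from the lymph node mean of 77.4% ± 0.637 (SD, n = 6). Isolated CpGs outside genes, with no other CpG within 75 bases, moved furthest. They averaged 81.3% ± 1.17 (SD, n = 6) in lymph node cells, 74.5% in TIM3neg cells, 72.5% in TIM3pos cells, and 67.7% (M9) and 69.4% (C6M9) at day 12. CpG-dense sequence, with 10 or more neighbours within 75 bases, went the other way, from 9.44% ± 0.184 (SD, n = 6) in lymph node cells to 11.3% in TIM3neg, 10.5% in TIM3pos, and 11.9% (M9) and 11.3% (C6M9) at day 12. Gene ends differed little, at 13.8% ± 0.175 (SD, n = 6), 14.7% and 13.9% in lymph node, TIM3neg and TIM3pos cells.

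**Figure D1:**
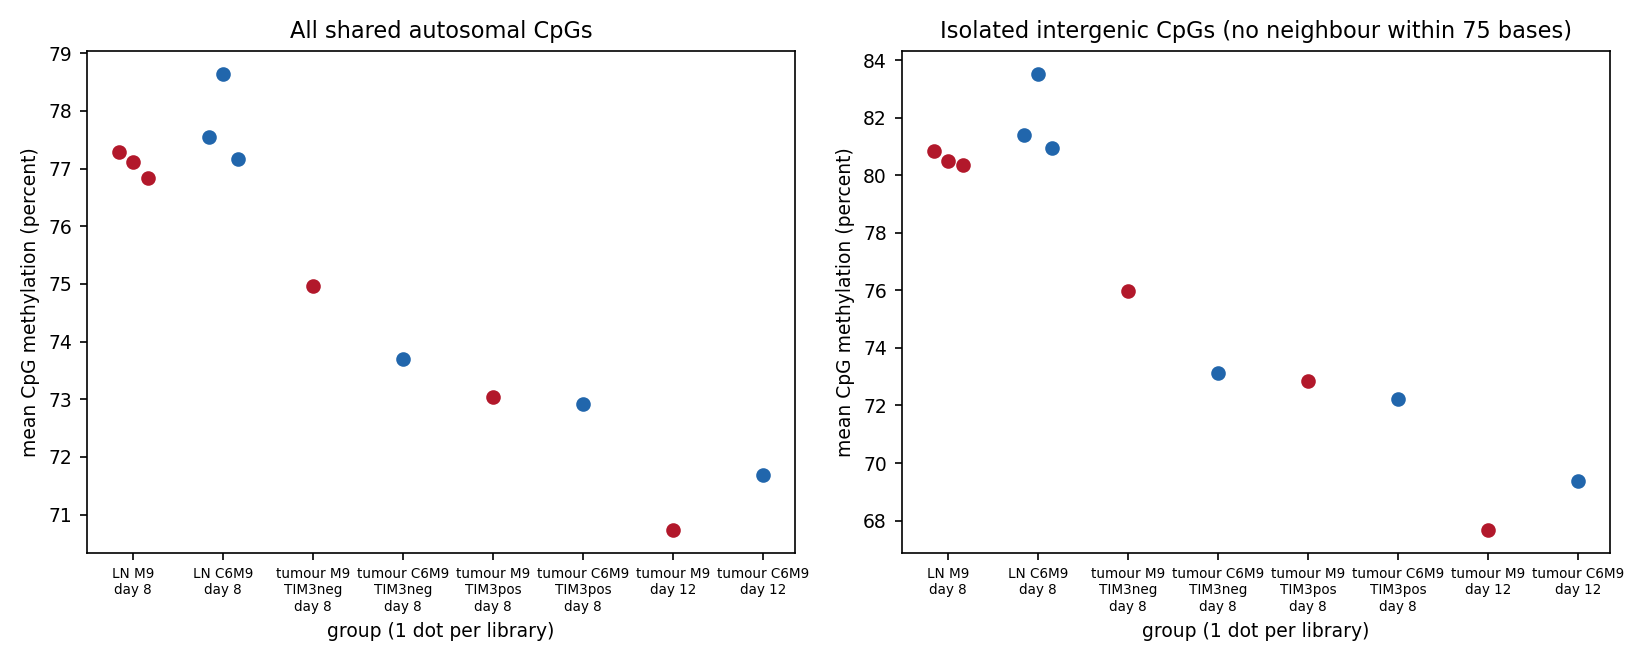
Mean CpG methylation in percent per library (1 dot each) by group, over all shared autosomal CpGs (left) and over isolated intergenic CpGs (right), with M9 in red and C6M9 in blue. All 6 lymph node libraries, from 76.8% to 78.6% over all CpGs, lie above all tumour libraries, from 70.7% to 74.96%.

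Lymph node cells under M9 and C6M9 were compared to see how antigen affinity relates to methylation outside the tumour. Regulators of progenitor and memory T cells differed at single tiles, in both directions. Bach2, a repressor that holds T cells in a memory-like state, was less methylated under M9 at chromosome 4, 32424001 to 32425000 (15.2% ± 2.49 against 39.9% ± 13.4, SD, n = 3 each). So was Slamf6 at chromosome 1, 171920001 to 171921000 (11.7% ± 2.71 against 30.4% ± 0.795). Lef1, a partner of Tcf7 in naive and memory cells, was more methylated under M9 at chromosome 3, 131171001 to 131172000 (70.3% ± 2.55 against 47.9% ± 2.85). Runx3, which directs the CD8 lineage, was less methylated at chromosome 4, 135177001 to 135178000 (35.1% ± 5.05 against 57.7% ± 5.81).

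Of 1675866 tiles tested, 1817 were called by the quasi-likelihood test, 455 higher and 1362 lower under M9. The tiles lay within genes in 71.2% (higher) and 59.0% (lower) of cases, against 46.8% of tested tiles. Their median levels of 53.4% and 57.15% lay below the 88.8% of tested tiles. An unadjusted p under 0.05 was found for 99632 tiles (5.95%). Limma on log2 ratios called 0 tiles, with 86758 at an unadjusted p under 0.05, and limma with read weights called 230. In simulated tiles of this and both day 8 tumour comparisons, limma without weights recovered 0% at 10, 20 and 30 points. Its 0 tiles therefore cannot test the calls. With read weights it recovered 58.2% at 20 points and 93.9% at 30 points in simulated lymph node tiles. No gene end (0 of 19456) and no gene body (0 of 19348) was called, with 1117 and 1476 at an unadjusted p under 0.05. Limma called 0 of both, weighted or not, with 1046 ends and 1187 bodies at an unadjusted p under 0.05. Without C6M9 replicate 2, the shallowest library, 1037 tiles were called, and without M9 replicate 2, 960. Without M9 replicate 1, 1 gene end was called. With the replicate number as a block 33 tiles were called, and without both replicate 2 libraries 413. Of 25 named tiles that were called, 9 kept their call without C6M9 replicate 2, 6 without both replicate 2 libraries, and 2 (Bach2 and Ripor2) with the block.

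Bach2 held the most differing sequence of any listed gene, with 9 tiles lower and 2 higher out of 327 tested. The Bach2 tile at 32424001 fell by 24.8 points (adjusted p = 1.27e-16), on 166 to 561 reads per library over 19 CpGs. It kept its call without any 1 library, as did the tiles of Lef1 (22.5 points, adjusted p = 9.95e-07), Runx3 (-22.6 points, adjusted p = 7.24e-05), Slamf6 (-18.6 points, adjusted p = 8.90e-05) and Ptpn22, a phosphatase that restrains receptor signalling (-19.5 points, adjusted p = 1.12e-07). Without both replicate 2 libraries Runx3 lost its call (-15.8 points).

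Genes of exhaustion and receptor signalling differed at further tiles. Tox, which drives exhaustion, was at 36.8% ± 3.02 against 55.6% ± 5.98 at chromosome 4, 6986001 to 6987000 (adjusted p = 0.0044). Tigit was at 57.1% ± 9.66 against 76.4% ± 6.49 at chromosome 16, 43661001 to 43662000 (adjusted p = 0.0329). Nfatc1 was at 15.8% ± 5.32 against 35.0% ± 12.85 at chromosome 18, 80711001 to 80712000 (adjusted p = 3.35e-04). Irf4, which scales with receptor signal strength, was at 29.96% ± 5.08 against 48.2% ± 5.14 at chromosome 13, 30756001 to 30757000 (adjusted p = 6.50e-04). Higher under M9 were Satb1 (68.5% ± 4.16 against 49.8% ± 3.75), Cd5 (77.1% ± 4.69 against 56.0% ± 7.09), Bcl11b (63.5% ± 6.405 against 44.4% ± 13.0) and the homing receptor gene Ccr9 (61.9% ± 8.36 against 41.2% ± 3.81), all SD, n = 3 each. Several of these calls were lost without C6M9 replicate 2, where the difference was -16.0 points at Tox, -16.7 at Tigit, -8.86 at Nfatc1, -15.25 at Irf4, 14.2 at Satb1, 12.0 at Cd5 and 7.97 at Bcl11b. Tox was also lost without C6M9 replicate 1 (-15.7), Nfatc1 without C6M9 replicate 3 (-19.8), and Ccr9 (15.9), Satb1 (16.7), Irf4 (-15.3), Cd5 (19.5) and Bcl11b (18.0) without M9 replicate 2. Tigit was further lost without C6M9 replicate 1 (-17.9), M9 replicate 1 (-17.6) and M9 replicate 3 (-15.4), Bcl11b without M9 replicate 1 (16.6) and C6M9 replicate 3 (21.1), and Cd5 without C6M9 replicate 3 (21.96). The imprinted gene Airn (-19.9 points) lost its call in every such removal (-22.2 to -13.0), and the B cell gene Cd22 (-18.8) without C6M9 replicate 2 (-17.4) or M9 replicate 3 (-14.1).

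The largest differences outside the lists included a tile within Mllt3, chromosome 4, 87979001 to 87980000 (23.0% ± 4.95 against 65.6% ± 18.7), and tiles near the coinhibitory receptor gene Btla (57.1 kb away, 9.67% ± 11.7 against 47.3% ± 13.3) and near the activation marker gene Cd83 (95.9 kb away, 31.8% ± 4.24 against 69.3% ± 17.0), all lower under M9. Cacna2d1 (-37.6 points) and 4933430I17Rik (-38.98 points) were lower too. Ripor2, a regulator of T cell polarity, was higher under M9 at chromosome 13, 24551001 to 24552000 (89.7% ± 1.56 against 62.5% ± 6.41, SD, n = 3 each, adjusted p = 3.61e-13), as were tiles near Tmem17 (155.8 kb away, 31.96 points), in Rapgef6 (29.6 points), in Scarb2 (29.0 points) and near Ddit4 (17.2 kb away, 27.7 points). Ripor2, 4933430I17Rik and Cd83 kept their calls without any 1 library, and Cd83 lost its call without both replicate 2 libraries (-20.7 points). Without C6M9 replicate 2, Mllt3 (-18.7), Btla (-20.8), Cacna2d1 (-14.2), Tmem17 (20.6), Rapgef6 (10.8), Scarb2 (14.0) and Ddit4 (16.4) lost theirs. Rapgef6, Scarb2 and Cacna2d1 tiles hold 3 CpGs and lost calls in 5, 5 and 3 of the single removals, with differences of 10.8 to 31.4, 14.0 to 30.6 and -36.1 to -14.2 points.

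The classical markers of the effector and exhausted states were not called at their ends or bodies in these lymph node cells. Gene bodies of Pdcd1 (75.9% ± 3.70 against 77.2% ± 4.47), Gzmb (90.3% ± 1.36 against 88.0% ± 5.01), Prf1 (89.99% ± 0.993 against 89.7% ± 0.934) and Havcr2 (81.7% ± 0.883 against 81.7% ± 1.61) were heavily methylated under both antigens. Gene ends of Tcf7 (2.50% ± 0.440 against 3.19% ± 1.28), Tbx21 (2.47% ± 0.876 against 2.25% ± 0.717), Prdm1 (5.13% ± 1.025 against 5.36% ± 0.952) and Id3 (7.82% ± 0.164 against 6.95% ± 0.562) were little methylated, all SD, n = 3 each. Among ends and bodies, the largest difference at a key gene was -7.03 points at the end of Pdcd1 (adjusted p = 0.898), followed by -4.83 points at the end of Ifng (20.4% ± 3.14 against 25.2% ± 4.29).

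Among the gene lists, loci with a lower tile under M9 were more frequent than in matched random lists for T cell receptor signalling (7 of 20 genes against a random mean of 1.15, one-sided adjusted p = 0.00433), exhaustion and inhibitory receptors (6 of 18 against 0.979, adjusted p = 0.00433) and effector and cytotoxic genes (5 of 22 against 0.685, adjusted p = 0.00433). The effector loci were Gzmk, Tnf, Il2, Tbx21 and Ccl5. Loci with a higher tile were more frequent for progenitor and memory genes (Lef1, Bach2 and Satb1; 0.344 at random, adjusted p = 0.0224), exhaustion genes (Nr4a2, Nr4a3 and Ikzf2; adjusted p = 0.0312), tissue residency (Itgae and Ccr9; adjusted p = 0.0224) and T cell identity (Runx3 and Bcl11b; adjusted p = 0.0295). Imprinted loci (Airn and Inpp5f) and B cell genes (Pax5 and Cd22) had 2 lower loci each, with adjusted p = 0.305 and 0.244. DNA methylation machinery, CD4 and regulatory T cell, myeloid, NK cell, and stromal and melanocytic lists had 0 loci in either direction. Called tiles had a median of 13 (higher) and 10 (lower) CpGs against 6 in tested tiles, which the random lists did not match. The locus counts were not repeated with the replicate block or without C6M9 replicate 2. Adjusted over the list alone, 1 effector gene end and 2 residency gene ends passed, and 0 ends or bodies of the other lists. Camera gave lower ends for exhaustion genes (adjusted p = 0.0449; adjusted p = 0.62 with an estimated correlation), and higher bodies for progenitor genes (0.0163; adjusted p = 0.62 with an estimated correlation) and residency genes (0.0146; adjusted p = 0.566 with an estimated correlation). No camera call of this or any later comparison held with an estimated correlation.

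**Figure D2:**
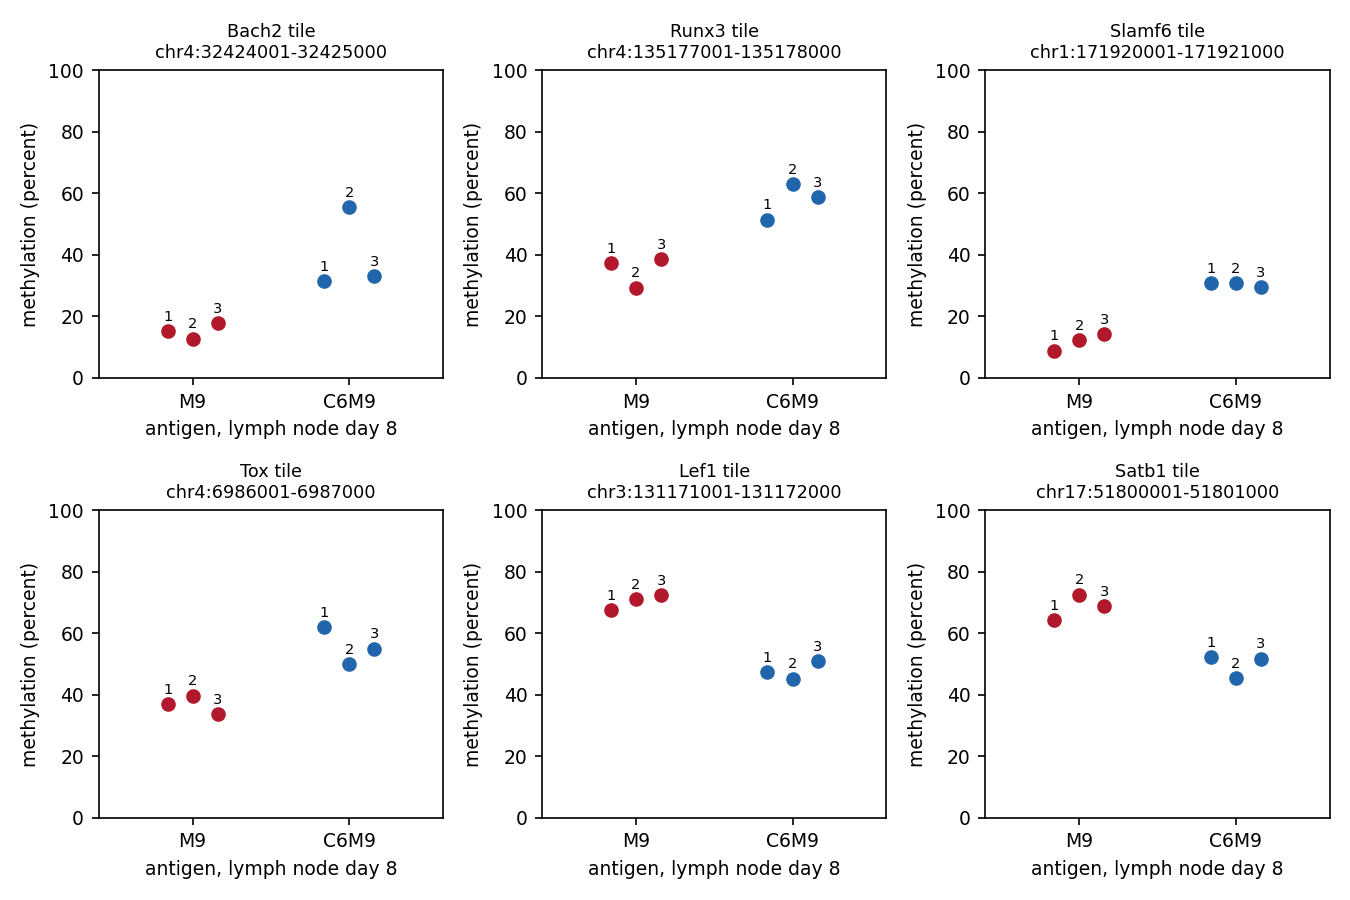
Methylation in percent of 6 tiles in lymph node libraries under M9 (red) and C6M9 (blue), each dot a library numbered by replicate. C6M9 replicate 2 is the highest C6M9 library at Bach2 (55.4%), while the 3 C6M9 libraries lie between 29.5% and 30.9% at Slamf6.

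TIM3pos and TIM3neg tumour cells were compared to describe how methylation differs between the progenitor and the terminally differentiated exhausted cells that these gates separate. Some genes of the cytotoxic programme were less methylated in TIM3pos cells, with 2 ends, 4 bodies and tiles at 13 loci called lower among 22 genes of the effector list. The body of Gzmb, which encodes granzyme B, was at 37.7% ± 2.04 in TIM3pos and 70.4% ± 0.900 in TIM3neg cells (SD, n = 2 each), and that of perforin, Prf1, at 62.7% ± 0.299 against 77.7% ± 4.67. Havcr2, the gene of Tim3 itself, was at 17.4% ± 4.17 against 41.6% ± 4.90 at its end. Tcf7, the transcription factor of progenitor cells, went the other way, with a tile at chromosome 11, 52271001 to 52272000 at 74.2% ± 0.913 in TIM3pos and 41.7% ± 2.76 in TIM3neg cells.

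The test called 1634 of 1588440 tiles, 119 higher and 1515 lower in TIM3pos cells. It called 32 of 19264 gene ends (2 higher, 30 lower) and 12 of 19290 gene bodies, all lower. The C6M9 TIM3neg library stood apart at many of the lower ends, among them Fzd6, Nfix, Hes6, Tmc7, Pkdrej, Pfdn4, Pde9a, Smoc2, Zfp354c, Htr1a and Irx3. Fzd6 was at 31.3% there, against 10.8% in M9 TIM3neg, 5.24% in M9 TIM3pos and 7.35% in C6M9 TIM3pos. Nfix was at 23.2% there, against 7.81%, 1.56% and 3.55% in the same order. Hes6 was at 23.8% there, against 6.83%, 3.16% and 4.42%, and at 0.631% to 2.71% in the lymph node libraries. Such calls cannot be told from a rise in that library alone. Other ends fell under both antigens, as at Tigit (82.6% to 62.1% under M9, 82.5% to 58.3% under C6M9). Limma called 0 tiles (82805 at an unadjusted p under 0.05), 1 end and 0 bodies (2282 at an unadjusted p under 0.05), and with read weights 471 tiles, 8 ends and 6 bodies. Leaving out either library of an antigen removes its pair from the comparison. Ends called then numbered 2 without C6M9 TIM3neg or C6M9 TIM3pos and 149 without M9 TIM3neg or M9 TIM3pos. No body (0) was called without any 1 of the 4. With the spread of the 4 tumour libraries only, 4 of 35 named regions kept their call, and without the 2 shallowest libraries 20.

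Havcr2 stood out at each kind of region. Its tile at chromosome 11, 46455001 to 46456000 was at 20.97% ± 4.56 in TIM3pos and 73.9% ± 15.5 in TIM3neg cells (SD, n = 2 each; adjusted p = 4.70e-08), and its body at 64.1% ± 0.487 against 77.0% ± 3.93. Tiles of Gzmb (-42.8 points), Prf1 (-36.3 points), Id2 (-28.4 points) and the ectonucleotidase gene Entpd1 (-28.3 points) kept their calls without any 1 library, as did the tiles of Havcr2 and Tcf7. Tiles of Prdm1 (15.8% ± 10.1 against 57.2% ± 5.98), Tbx21 (18.4% ± 1.48 against 48.0% ± 5.02), Klrg1 (24.6% ± 5.82 against 56.1% ± 4.54) and Il2ra (36.9% ± 8.08 against 73.2% ± 13.1) were also lower in TIM3pos cells. So was a tile shared by the neighbouring chemokine genes Ccl3 and Ccl4 (32.4% ± 2.07 against 59.6% ± 6.25). These were lost on the C6M9 pair alone, without either M9 library, at -29.95 points (Prdm1), -25.0 (Tbx21), -30.5 (Klrg1), -21.3 (Il2ra) and -30.1 (Ccl3 and Ccl4). Rgs1 (31.1% ± 2.34 against 66.1% ± 0.737) was lost without any 1 tumour library (-36.2 to -32.9 points).

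Gene ends lower in TIM3pos cells included those of the costimulatory receptors Tnfrsf9 (52.9% ± 3.75 against 84.1% ± 4.76, SD, n = 2 each; adjusted p = 0.00593) and Tnfrsf4 (-18.4 points), of Tigit (60.2% ± 2.65 against 82.5% ± 0.0721; adjusted p = 0.0199), of Gzmb (7.85% ± 1.96 against 28.4% ± 5.46; adjusted p = 0.00418) and of Prf1 (8.37% ± 1.29 against 20.1% ± 1.68; adjusted p = 0.0198). Src (42.9% ± 0.998 against 30.1% ± 1.91) and Gnas (48.7% ± 3.17 against 37.3% ± 1.701) were the 2 higher ends. Gzmb lost its call without C6M9 TIM3neg (-17.2) or C6M9 TIM3pos (-18.1), Havcr2 (-17.7) and Tnfrsf9 (-25.2) without M9 TIM3neg or M9 TIM3pos. Without any 1 of the 4 tumour libraries the calls were lost at Tigit (-24.1 to -20.5 points), Tnfrsf4 (-18.5 to -18.3), Prf1 (-12.05 to -11.5), Src (9.14 to 13.4) and Gnas (10.4 to 14.1). The same holds for the bodies of Gzmb (-33.5 to -31.0), Prf1 (-19.2 to -11.45), Havcr2 (-16.0 to -9.79) and Tbx21 (39.2% ± 2.54 against 51.7% ± 0.0599; -14.4 to -10.5).

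By size alone, tiles in Fmnl2 (9.86% ± 0.481 against 65.2% ± 25.65, on 3 CpGs and 18 to 49 reads), Sv2c (27.2% ± 7.78 against 75.5% ± 11.3), Atm (23.8% ± 11.7 against 69.1% ± 1.21) and the splicing factor gene Sf3b3 (19.1% ± 0.0286 against 63.7% ± 1.52) were lowest in TIM3pos relative to TIM3neg cells (SD, n = 2 each). Tiles higher in TIM3pos cells lay near Hs3st1 (796 kb away, 37.9 points), Pou3f2 (182.6 kb away, 37.1 points) and Gata3 (616 kb away, 34.4 points), within the Wnt receptor regulator Znrf3 (30.6 points) and at Tcf7. An Airn tile was lower by -29.5 points. Sv2c, Sf3b3 and Airn kept their calls without any 1 library. Fmnl2 (-37.5) and Hs3st1 (22.3) were lost without either C6M9 library, Atm (-37.9) and Znrf3 (21.3) without either M9 library, Gata3 without either M9 library (26.5) or C6M9 TIM3neg (30.9), and Pou3f2 without any 1 (34.2 to 39.9).

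Other key genes were not called at their ends or bodies between the subsets. The Pdcd1 body was at 39.2% ± 2.69 in TIM3pos and 43.0% ± 3.50 in TIM3neg cells, far below its lymph node level, and Tox (77.4% ± 0.609 against 76.9% ± 1.33) and Bach2 (74.2% ± 0.00750 against 74.3% ± 0.663) were alike. The Slamf6 body was at 63.4% ± 2.30 against 60.4% ± 1.22, although its product Ly108 was used to sort the cells. The bodies of Tcf7 (50.9% ± 1.56 against 44.0% ± 1.89; adjusted p = 0.0327) and Ifng (52.5% ± 2.22 against 66.5% ± 2.65; adjusted p = 0.0572) and the end of Tbx21 (5.04% ± 2.92 against 9.74% ± 5.87; adjusted p = 0.0341) missed a threshold of size or of p (SD, n = 2 each).

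The effector and cytotoxic list had 13 of 22 genes with a lower tile, against 0.872 in random lists (one-sided adjusted p = 0.0013), among them Ifng, Gzmk, Ccl5 and Il12rb2. Exhaustion genes had 5 (Pdcd1, Havcr2, Tigit, Entpd1 and Irf4; 1.11 at random, adjusted p = 0.0208) and residency genes 4 of 13 (Cxcr6 and Zfp683 among them; 0.42 at random, adjusted p = 0.0052). Progenitor genes had 3 loci with a higher tile (Tcf7 with 6 of 44 tiles, Lef1 and Bach2; 0.0763 at random, adjusted p = 0.0013) and 0 with a lower one. Receptor signalling had 4 lower loci (Egr1 and Cblb among them; adjusted p = 0.204). T cell identity (Runx3), CD4 markers (Tnfrsf4), stromal markers (Pdgfra) and imprinted loci (Airn) had 1 lower locus each, and the methylation machinery, B cell, myeloid and NK cell lists 0. Over all genes 2 effector ends and 4 effector bodies were called, and adjusted over the list alone 5 ends and 7 bodies. For exhaustion genes these were 2 ends and 1 body, and 3 ends adjusted over the list alone. Camera gave lower effector ends (adjusted p = 2.94e-06; adjusted p = 0.0543 with an estimated correlation), lower effector bodies (1.24e-05; adjusted p = 0.345 with an estimated correlation) and higher progenitor bodies (5.42e-05; adjusted p = 0.332 with an estimated correlation).

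The 1515 tiles lower in TIM3pos cells had median levels of 67.9% to 73.2% in the 6 lymph node libraries, 60% to 62.1% in TIM3neg cells, and 36.2% (M9) and 41.2% (C6M9) in TIM3pos cells. In the day 12 libraries, which took no part in choosing them, the medians were 43.5% (M9) and 42.7% (C6M9). The 119 higher tiles were at 58.5% to 65.0% in lymph node, 54.0% (M9) and 52.6% (C6M9) in TIM3neg, 74.9% and 72.6% in TIM3pos, and 70.2% and 72.2% at day 12.

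**Figure D3:**
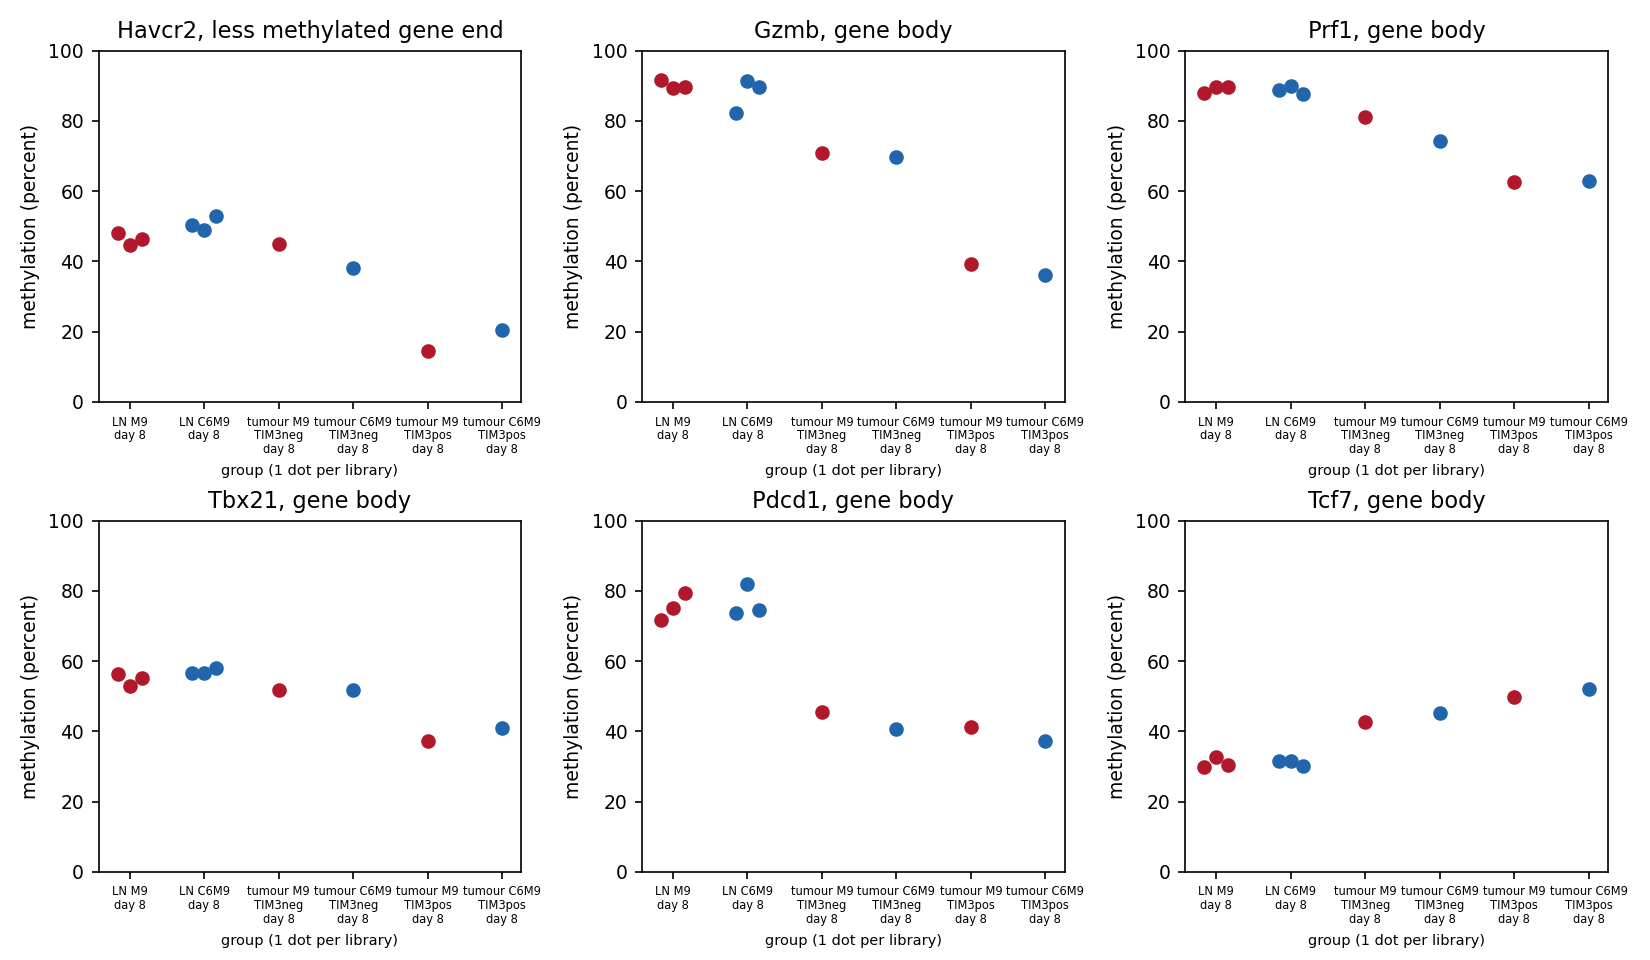
Methylation in percent of 1 gene end and 5 gene bodies in the 10 day 8 libraries (1 dot each) by group, with M9 in red and C6M9 in blue. The Gzmb body is at 70.4% in TIM3neg and 37.7% in TIM3pos cells, and the Pdcd1 body at 43.0% and 39.2% against 76.1% in lymph node cells (means).

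M9 and C6M9 were also compared within the day 8 tumour, to see how antigen affinity relates to methylation of exhausted cells. Tiles of T cell identity and receptor signalling genes were among those that were lower under M9. A tile at Thy1, which encodes CD90, chromosome 9, 44044001 to 44045000, was at 4.14% ± 1.95 under M9 and 24.6% ± 4.39 under C6M9 (SD, n = 2 each). Tiles of the receptor modulators Cd5 (9.54% ± 0.600 against 25.2% ± 1.16) and Cd6 (25.5% ± 2.74 against 52.2% ± 0.0327) and of Ikzf2, which encodes Helios (20.8% ± 8.07 against 53.3% ± 10.9), were lower too. Satb1 (81.0% ± 2.78 against 61.3% ± 7.21) and Nfatc2 (77.0% ± 3.48 against 59.8% ± 8.82) were higher.

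The test called 877 of 1588440 tiles (304 higher, 573 lower under M9) and 49 of 19264 gene ends (6 higher, 43 lower). Over all tested tiles the mean difference was positive, at 1.02 points (median 0.688), although more called tiles were lower. No gene body (0 of 19290) was called, with 1567 at an unadjusted p under 0.05. Limma called 0 tiles (78538 at an unadjusted p under 0.05), 0 ends (1697) and 0 bodies (1244), and with read weights 76, 15 and 0. Of the lower tiles, 22.7% lay at gene ends, against 2.58% of tested tiles, and their median level was 17.25%. Tiles called numbered 2841 without M9 TIM3pos and 2839 without C6M9 TIM3pos. Ends numbered 201 and 199 without these, and 21 and 25 without M9 TIM3neg and C6M9 TIM3neg.

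The C6M9 TIM3neg library was raised at little methylated ends of T cell genes. Over 22 ends of T cell identity and receptor signalling genes, its median excess over the lymph node mean was 5.59 points, with 19 ends raised, against 0.505 in M9 TIM3neg, -0.380 in M9 TIM3pos, 1.00 in C6M9 TIM3pos and -1.10 to 1.14 in the lymph node libraries. Cd3e was at 24.5% in this library (lymph node 3.78% ± 1.88, SD, n = 6), Runx3 at 18.5% (4.52% ± 0.895) and Thy1 at 14.99% (6.85% ± 1.46), while Cd3d (9.38%) and Cd3g (8.14%) were at their lymph node levels (8.80% ± 1.69 and 8.88% ± 2.36). The day 12 libraries were raised likewise, by 5.35 points (M9) and 3.29 points (C6M9).

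**Figure D4:**
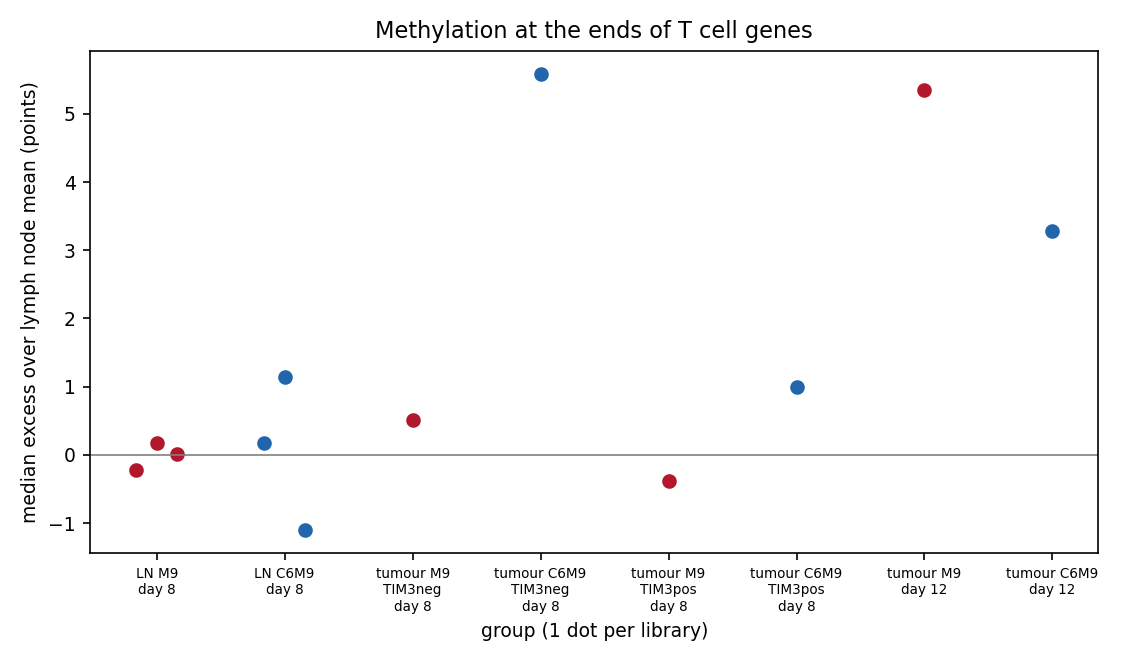
Median excess in percentage points, over the lymph node mean, of methylation at 22 ends of T cell identity and receptor signalling genes per library (1 dot each), with M9 in red and C6M9 in blue. C6M9 TIM3neg (5.59 points) and the day 12 libraries (5.35 and 3.29 points) lie above all other libraries, which reach at most 1.14 points.

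By list, lower loci under M9 were more frequent for receptor signalling (6 of 20: Nfatc1, Nfatc2, Cblb, Dgkz, Cd5 and Cd6; 0.731 at random, one-sided adjusted p = 0.0052) and T cell identity (3 of 10: Cd3e, Cd8b1 and Thy1; 0.2 at random, adjusted p = 0.0104). The C6M9 TIM3neg library was itself raised at ends of these lists, by 5.59 points against 1.00 in C6M9 TIM3pos. Locus counts and camera were not repeated without that library, so how much of their results it gives is open. Exhaustion genes (Nfatc1, Batf and Ikzf2) and effector genes (Gzmk, Tnf and Il2ra) had 3 each (adjusted p = 0.117), B cell genes 2 (Pax5 and Cd22; adjusted p = 0.117) and progenitor genes 2 (Tcf7 and Lef1), while Satb1 was the 1 progenitor locus with a higher tile. The methylation machinery (Dnmt3a), CD4 markers (Tnfrsf4), myeloid markers (Fcgr3) and imprinted loci (Meg3) had 1 lower locus each, Plagl1 was the 1 higher imprinted locus, and residency, NK cell and stromal lists had 0. Adjusted over the list alone, 2 identity ends and 2 signalling ends passed. Camera gave lower ends for effector genes (adjusted p = 2.70e-04; adjusted p = 0.121 with an estimated correlation), T cell identity (6.15e-04; adjusted p = 0.411 with an estimated correlation) and receptor signalling (0.0155; adjusted p = 0.685 with an estimated correlation). It gave lower bodies for receptor signalling (0.00501; adjusted p = 0.685 with an estimated correlation) and T cell identity (0.011; adjusted p = 0.685 with an estimated correlation).

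Among named regions the Thy1 tile kept its call without any 1 library (adjusted p = 6.51e-05 with all), as did a tile in Pole4 (62.4% ± 1.34 against 88.7% ± 2.97, SD, n = 2 each; adjusted p = 3.61e-04). Thy1 lost its call without the 2 shallowest libraries (-12.1 points), where 6 of 33 named regions kept theirs, and with the spread of the 4 tumour libraries only 0 of 33 did. Without C6M9 TIM3neg the difference was -14.6 points at Ikzf2, -5.08 at Nfatc1 (22.6% ± 2.89 against 42.8% ± 11.85 with all), -2.60 at Dgkz (4.83% ± 1.06 against 18.4% ± 14.4) and -9.96 at Dnmt3a (18.6% ± 4.43 against 34.4% ± 4.73), and none of these was called. Ikzf2 (-19.1), Nfatc1 (-9.83) and Dgkz (-4.18) were also lost without M9 TIM3neg, and Dnmt3a without M9 TIM3pos (-14.5) or C6M9 TIM3pos (-16.0). Cd5 (-16.05), Plagl1 (13.4), Meg3 (-15.4) and Tnfrsf4 (-13.8) were lost without either TIM3pos library, and Nfatc2 without M9 TIM3neg (13.5) or C6M9 TIM3neg (12.65). Cd6 (-28.6 to -24.7), Satb1 (16.5 to 22.8), Prkcq (13.8 to 16.1), Pax5 (-16.3 to -15.4) and Fcgr3 (-17.4 to -13.2) were lost without any 1 tumour library.

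The gene ends with the largest differences were Pi15 (82.8% ± 1.26 against 57.6% ± 3.12), Ccdc70, Cavin2, 1700011L22Rik and Elf3, higher under M9 by 25.2 to 10.6 points, and Erfe (15.65% ± 2.12 against 33.7% ± 16.2), Shtn1, Fmn2 (7.60% ± 0.238 against 24.3% ± 16.6), Gpr176 and Des, lower by -18.0 to -15.7 points (SD, n = 2 each). Each of these 10 lost its call without at least 1 tumour library. At a minimum of 10 reads 1700011L22Rik (-1.08) and Des (2.55) turned direction and were not called. Without C6M9 TIM3neg the differences were 3.43 (Ccdc70), 8.11 (1700011L22Rik), -8.54 (Erfe), -10.45 (Shtn1), -1.95 (Fmn2), -13.3 (Gpr176) and -4.28 points (Des). Without M9 TIM3neg they were 9.32, 9.06, -8.08, -11.01, -4.82, -13.3 and -6.95 points in the same order, and all 7 were lost in both. Ccdc70 (22.9), 1700011L22Rik (14.2) and Gpr176 (-20.02 to -19.45) were lost without either TIM3pos library too. Pi15 (22.1 to 28.3), Cavin2 (11.7 to 16.75) and Elf3 (8.60 to 12.6) were lost without any 1. Tiles near Aga (37.97 points), Lrriq3 (37.2), Gria2 (36.1) and Fzd3 (35.97) and in Creb5 (36.5) were highest, and those in Ece1 (-36.3) and near Arhgef3 (-28.15) lowest, relative to C6M9, all on 3 to 5 CpGs. Ece1 (-21.3), Arhgef3 (-13.95), Fzd3 (26.3) and Aga (39.1) were lost without C6M9 TIM3neg, and Lrriq3 (34.4 to 39.99), Creb5 (32.9 to 40.1) and Gria2 (34.3 to 37.9) without any 1.

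The key genes were not called at their ends or bodies between the antigens in the tumour. Bodies of Tcf7 (46.2% ± 5.03 against 48.6% ± 4.69), Pdcd1 (43.3% ± 3.11 against 38.9% ± 2.31), Gzmb (55.1% ± 22.5 against 53.0% ± 23.7) and Tox (77.9% ± 0.00786 against 76.5% ± 0.714) and the end of Havcr2 (29.7% ± 21.6 against 29.2% ± 12.5) were close, with the spread at Gzmb and Havcr2 set by the TIM3 subsets. The ends of Tbx21 (4.28% ± 1.84 against 10.5% ± 4.80; adjusted p = 0.00335) and Prdm1 (6.73% ± 2.26 against 12.6% ± 3.07; adjusted p = 0.0257) were lower under M9 by less than 10 points (SD, n = 2 each).

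TIM3neg tumour cells were compared with lymph node cells to describe how the progenitor exhausted cells of the tumour differ from activated cells of the lymph node, although the sorting gates differ too. Pdcd1, the gene of PD1, was less methylated in the tumour, at 43.0% ± 3.50 (SD, n = 2) against 76.1% ± 3.90 (SD, n = 6) over its body, with 16 of 18 tiles lower. Bodies of 6 effector genes were called lower as well, among them Gzmb at 70.4% ± 0.900 against 89.0% ± 3.44, Ifng at 66.5% ± 2.65 against 85.0% ± 3.12 and Prf1 at 77.7% ± 4.67 against 88.9% ± 0.947 over their bodies. Tcf7 was more methylated, at 44.0% ± 1.89 against 31.1% ± 1.07 over its body, with 20 of 44 tiles higher.

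The test called 87097 of 1591929 tiles, 7324 higher and 79773 (91.6%) lower in the tumour. It called 645 of 19276 gene ends (347 higher, 298 lower) and 242 of 19294 bodies (40 higher, 202 lower). Limma called 1059 tiles, 754 ends and 402 bodies, and with read weights 40179, 510 and 213. Lower tiles lay within genes in 39.3% and higher tiles in 69.6% of cases, against 47.5% of tested tiles, and 10.98% of the higher tiles lay at gene ends against 2.58%. Tiles called numbered 19870 without C6M9 TIM3neg. Ends numbered 167 without C6M9 TIM3neg and 1153 without M9 TIM3neg, and bodies 43 and 756. Mean differences over all tested tiles were -3.99 points here, against -1.42 between TIM3pos and TIM3neg cells, -0.854 between the lymph node groups and 1.02 between antigens in the tumour.

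At Pdcd1 a tile at chromosome 1, 94050001 to 94051000 was at 15.7% ± 14.9 in the tumour and 71.8% ± 3.43 in the lymph node (adjusted p = 9.91e-07), and the gene end at 24.5% ± 1.59 against 44.3% ± 6.37 (-13.7 points and not called without the 2 shallowest libraries). Bach2 was lower at chromosome 4, 32391001 to 32392000 (26.0% ± 5.74 against 72.7% ± 5.49; adjusted p = 5.06e-11), with 25 of its 325 tiles lower and 5 higher. Ikzf2 (29.9% ± 0.0200 against 73.0% ± 9.15), Irf4 (26.5% ± 9.60 against 67.0% ± 9.76), Tbx21 (48.0% ± 5.02 against 87.5% ± 8.44), Ccl5 (53.5% ± 8.19 against 94.6% ± 2.76), Cx3cr1 (22.4% ± 15.3 against 65.4% ± 4.77), Xcl1 (45.3% ± 3.01 against 84.7% ± 6.11) and Cblb (40.5% ± 9.85 against 77.7% ± 6.90) each had a lower tile in the tumour, as did the cytokine receptor genes Il2ra (-46.7 points) and Il12rb2 (-44.5 points) and the imprinted gene Airn (-47.6 points), with n = 2 and n = 6 (SD). All of these kept their calls without any 1 library. The tile of Ccl3 and Ccl4 (-35.3) lost its call without M9 TIM3neg (-26.7), as did the end (-23.5; -17.5 without it) and body (-18.2 without it) of Gzmb. Tnf (-34.8) lost its call without C6M9 TIM3neg (-23.7), and the Prf1 body fell under 10 points without it (-8.245) or without lymph node C6M9 replicate 2 (-9.18).

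A stretch around Myc and the long non-coding RNA Pvt1 on chromosome 15 held some of the largest changes in both directions. Tiles at 62028001 (16.5% ± 10.1 against 80.1% ± 3.24), 62049001 within Pvt1 (28.2% ± 15.02 against 92.3% ± 3.57) and 62287001 (16.7% ± 5.34 against 81.0% ± 5.66) were lower in the tumour. Tiles at 62169001 within Pvt1 (57.95% ± 10.2 against 2.48% ± 1.38) and 61651001 (69.3% ± 12.5 against 24.6% ± 7.60) were higher. The largest fall was near Saraf, 54.15 kb away on chromosome 8 (18.5% ± 1.16 against 88.1% ± 5.29; adjusted p = 2.70e-18), followed by Ric1 (-63.2 points). Higher tiles also lay in Ptprk (65.3% ± 2.64 against 23.1% ± 5.49), in Fmnl2 (51.6 points; 31.5 and not called without C6M9 TIM3neg) and in Enthd1 (41.9 points; 25.9 and not called without it).

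Gene ends raised in the tumour included B3galt2 (22.25 points), Siglecg (20.65), Tomm20l (20.4) and Chil5 (19.6). Those lowest were Tdpoz3 (-32.85 points), Xdh (39.1% ± 0.958, n = 2, against 71.0% ± 4.04, n = 6; SD), Apon (-29.6), Olr1 (-28.6) and H2-M10.4 (-28.35). Xdh, Apon and Olr1 kept their calls without any 1 library. Without C6M9 TIM3neg, B3galt2 (15.4), Siglecg (23.3), Tomm20l (14.2), Chil5 (22.1), Tdpoz3 (-14.6) and H2-M10.4 (-22.9) were lost, and without M9 TIM3neg B3galt2 (26.1), Siglecg (18.0), Chil5 (17.1) and H2-M10.4 (-33.8). Chil5 was further lost without lymph node C6M9 replicate 2 (10.55), C6M9 replicate 1 (18.9), M9 replicate 1 (19.4) or M9 replicate 3 (18.0).

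Small changes at key gene ends stayed under 10 points. Tbx21 was at 9.74% ± 5.87 in the tumour and 2.39% ± 0.673 in the lymph node (adjusted p = 1.84e-04), Prdm1 at 11.55% ± 4.56 against 5.25% ± 0.893 (adjusted p = 0.00367) and Tcf7 at 6.23% ± 2.45 against 2.91% ± 0.982 (adjusted p = 0.00442; SD, n = 2 and n = 6). The bodies of Tox (76.95% ± 1.37 against 81.5% ± 1.41; adjusted p = 0.00693), Havcr2 (77.0% ± 3.93 against 82.3% ± 1.18; adjusted p = 0.0293) and Slamf6 (60.4% ± 1.22 against 65.8% ± 2.13; adjusted p = 0.0361) were lower by -5.41 to -4.53 points. Id3 (7.90% ± 2.68 against 7.48% ± 0.597) and Havcr2 (41.6% ± 4.90 against 48.7% ± 2.91) were not called at their ends.

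By list, loci with a higher tile in TIM3neg tumour cells were more frequent for progenitor and memory genes (13 of 18 against 3.86 at random, one-sided adjusted p = 6.50e-04), receptor signalling (14 of 20 against 5.55, adjusted p = 6.50e-04), T cell identity (8 of 10 against 1.71, adjusted p = 6.50e-04) and tissue residency (8 of 13 against 1.7, adjusted p = 6.50e-04). The excess at ends of identity and signalling genes given above was 5.59 points in C6M9 TIM3neg and 0.505 in M9 TIM3neg, and called tiles fell from 87097 to 19870 without C6M9 TIM3neg. Loci with a lower tile were more frequent for exhaustion genes (16 of 18 against 10.6, adjusted p = 0.0119), effector genes (17 of 22 against 9.72, adjusted p = 0.0078) and receptor signalling (18 of 20 against 12.3, adjusted p = 0.0119). The methylation machinery (6 of 7 lower; adjusted p = 0.643) and imprinted loci (10 of 16 lower; adjusted p = 0.607) were near their random frequency. So were lower loci in 2 of 4 CD4 marker genes (1.85 at random), 7 of 9 B cell genes (4.82; adjusted p = 0.259), 6 of 10 myeloid genes (4.29), 3 of 6 NK cell genes (2.25) and 5 of 11 stromal and melanocytic genes (5.855; Mitf, Pmel, Dct, Col1a1 and Pdgfrb). Over all genes 6 effector bodies were called lower. Progenitor genes had 1 higher and 1 lower call at ends and at bodies, and adjusted over the list alone 3 ends and 2 bodies. Camera gave higher ends for progenitor genes (adjusted p = 0.0013; adjusted p = 0.358 with an estimated correlation) and residency genes (0.0342; adjusted p = 0.564 with an estimated correlation). It gave higher bodies for T cell identity (0.00101; adjusted p = 0.564 with an estimated correlation) and progenitor genes (0.0023; adjusted p = 0.358 with an estimated correlation), and lower bodies for effector genes (0.0342; adjusted p = 0.767 with an estimated correlation).

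Groups of 1 library were compared without a test, to describe the day 12 tumour and the single subsets. At day 12 several genes of exhaustion and cytotoxicity had close levels over their bodies, while the ends of Havcr2, Prf1, Tox, Tcf7 and Bach2 were higher under M9. The Gzmb body was at 29.2% under M9 and 31.6% under C6M9, Prf1 at 51.0% and 51.2%, Pdcd1 at 38.8% and 40.1%, and Tcf7 at 56.9% and 57.0%. The end of Havcr2 was at 19.9% (95% Wilson interval 17.4 to 22.6) under M9 and 14.8% (12.6 to 17.3) under C6M9, that of Prf1 at 21.4% (19.15 to 23.9) and 15.96% (13.95 to 18.2), that of Tox at 25% (22.97 to 27.1) and 20.9% (19.1 to 22.8), and that of Tcf7 at 8.01% (7.34 to 8.73) and 5.87% (5.34 to 6.45), with no interval shared. That of Bach2 was at 15.99% (14.97 to 17.1) and 13.3% (12.3 to 14.25). Tox went the other way over its body, at 75.6% (75.3 to 75.85) under M9 and 77.7% (77.4 to 77.97) under C6M9. The Ifng body was at 41.8% (39.7 to 43.9) and 46.4% (44.3 to 48.6). Of 2085016 tiles, 59 differed by at least 30 points (28 higher, 31 lower under M9), and 0 of 20315 gene ends. Pairs of lymph node libraries of 1 group, which are shallower, gave 385 to 1578 tiles and 1 to 8 ends. With every tile thinned to 20 CpG read observations, 81342 (3.90%) differed at day 12, against 1.86% to 2.07% in the lymph node pairs. At 20 observations sampling alone gives many such gaps, and how many depends on the methylation level. The day 12 libraries were less methylated than the lymph node libraries, so these shares cannot be read as an antigen difference. The largest ends were Gm3476 (33.3% against 60.2%), Oog2, Csn1s2a, Olfr329 and Vmn2r37, lower under M9, and Vmn2r42 (63.8% against 46.7%), Gm8251, Olfr1316, Klrc3 and Olfr1251, higher. The ends of T cell identity genes were higher under M9 at day 12, with a median of 3.90 points at percentile 99.96 of random lists, as were those of receptor signalling (2.56 points), residency (2.41 points) and progenitor genes (1.69 points, percentile 99.58), and those of NK cell markers (3.32 points, percentile 99.24). The excess of T cell gene ends over the lymph node mean was itself larger in the M9 than in the C6M9 day 12 library (5.35 against 3.29 points).

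Within the day 8 tumour, TIM3pos cells were below TIM3neg cells at the ends of effector genes under each antigen. The median difference was -6.05 points under M9 (percentile 0.00 of 10000 random lists) and -5.55 points under C6M9 (percentile 0.08), and over effector bodies it was -3.92 and -4.32 points. Ends of T cell identity genes were lower too, by -6.35 points under C6M9 (percentile 0.27, 10 of 10 lower) and -1.62 points under M9 (percentile 1.82), as were those of NK cell markers under M9 (-5.19 points, percentile 3.33, 6 of 6 lower). Progenitor ends were lower in TIM3pos cells under C6M9, by -3.53 points (percentile 0.25), and by -0.582 points (percentile 28.8) under M9. Progenitor bodies lay above random lists under both, with medians of 0.264 and 1.09 points (percentiles 99.73 and 99.82). Tiles that differed by at least 30 points numbered 1098 between TIM3pos and TIM3neg under M9 (141 higher, 957 lower) and 4716 under C6M9 (2552 higher, 2164 lower), with 9 and 14 gene ends. Between M9 and C6M9 there were 5605 tiles in TIM3neg (5046 higher, 559 lower) and 1048 in TIM3pos cells (702 higher, 346 lower), with 15 and 4 gene ends. Both counts that hold the shallow C6M9 TIM3neg library exceed the others. Effector ends were lower under M9 in TIM3pos cells by -3.59 points (percentile 0.00) and in TIM3neg cells by -4.39 points (percentile 0.9), and T cell identity ends in TIM3neg cells by -5.06 points (percentile 1.06). In TIM3pos cells the ends of identity genes were lower by -2.16 points (percentile 1.26), of receptor signalling genes by -2.14 points (percentile 1.08) and of progenitor genes by -1.30 points (percentile 1.39). The C6M9 TIM3neg library was itself raised at T cell gene ends, by 5.59 points over the lymph node mean against 0.505 in M9 TIM3neg. It enters the list differences given under C6M9 and those given in TIM3neg cells.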

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

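The tests of raised T cell gene ends, of isolated CpGs and of tile splits, and the tests that leave out a shallow library, were chosen after the result was seen, and the others before.

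An interaction test of M9 minus C6M9 in TIM3neg tumour cells against the same difference in lymph node cells called 2081 tiles (940 positive, 1141 negative) and 72 gene ends. All 72 ends were negative, for example Podxl (-18.6 points in the tumour, 0.519 in the lymph node, adjusted p = 5.09e-04), Chn2 (-21.2 and 0.188), Erfe (-27.9 and 0.608) and Fzd6 (-20.5 and 0.480). The same kind of test of TIM3pos minus TIM3neg under M9 against C6M9 called 852 tiles (439 positive, 413 negative) and 11 gene ends. All 11 ends were positive, for example Vax1 (2.86 points under M9, -17.4 under C6M9, adjusted p = 0.0134), Chn2 (2.12 and -16.8) and Kdf1 (5.11 and -20.2). No gene body was called for either (0, with 1871 and 719 at an unadjusted p under 0.05). Each tumour arm is 1 library, so the p-values rest on the spread of the lymph node libraries and cannot separate an effect of antigen or TIM3 state from one of a single library. Both contrasts include the shallow C6M9 TIM3neg library, which is the highest at the end of Podxl (21.6%, against 3.04%, 3.86% and 6.38% in the other day 8 tumour libraries).

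Data outside the comparisons held 2 signals. Coverage of chromosome Y relative to the autosomes ran from 0.0270 in lymph node M9 replicate 2 to 0.225 in lymph node M9 replicate 3. CpGs of the mitochondrial genome, at a mean coverage of 160 to 185 reads, were read as methylated at 43.9% in M9 TIM3pos to 52.6% in lymph node C6M9 replicate 1. That coverage varied little while autosomal coverage of the day 8 libraries ran from 6.08 to 22.0 reads, and it lay near the coverage ceiling. Whether these levels reflect the DNA or the way reads were counted was not tested.

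The ends of T cell genes in the C6M9 TIM3neg library lay 5.59 points above the lymph node mean, and random ends reached 2.61 points at the 95th percentile. Incomplete bisulfite conversion does not account for them, since ends under 2% in every lymph node library rose by only 0.133 points. Shallow sequencing alone did not give as much in the shallower lymph node C6M9 replicate 2, which had an excess of 1.14 points. That was the highest of the 6 lymph node libraries, with 17 of 22 ends raised, so a part for depth is not excluded. DNA of other cell types cannot be told apart from a difference of the T cells themselves, for which no biological explanation was tested, since the excess is the pattern itself and ends of stromal (-0.157 points), myeloid (-0.282 points) and B cell markers (2.45 points) were not below all lymph node libraries, those of B cells lying above all 6. The M9 day 12 library (5.35 points) and the C6M9 day 12 library (3.29 points) share the excess, and those cells were labelled only CD8. The C6M9 TIM3neg cells were labelled CD8CD90.1PD1+Ly108+Tim3-, a narrower gate.

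The lower methylation of TIM3neg tumour cells was measured in the M9 library at tiles chosen from the C6M9 libraries, where the median fall was 5.36 points. Unmethylated DNA of other cells at a share of 6.34%, the upper level in that library of the 2329 ends under 2% in every lymph node library, could give 5.59 points, but for tiles chosen from M9 and measured in C6M9 the fall of 14.1 points exceeds the 10.9 that a share of 12.4% could give. For tiles with the strongest loss the fall of 8.17 points exceeds the possible 5.22, so such DNA is neither excluded nor supported. The shallow C6M9 TIM3neg library does not carry the direction, since 88.5% of called tiles were lower without it. Loss at isolated CpGs, as after many cell divisions, was the biological explanation tested and stays open, since its test, a loss of at least 1.75 points more than at CpGs with 1 or 2 neighbours (lymph node libraries differ by -0.332 to 0.815 points), repeats what had been seen.

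The lymph node tiles that differ between antigens numbered 1817, and 1 of the 10 splits of the 6 libraries, the real one, gave as many, with 574 in the highest other split. For gene ends (0, highest other 1) and bodies (0, highest other 0) all 10 splits gave as many, and with 10 splits no share can go under 0.1. One pair of libraries is not the only source of the direction, since tiles called from 2 pairs had the same direction in the third in at least 81.4% (50.9% of all tested tiles), but 1037 were called without the shallow C6M9 replicate 2 and 303 without pair 2 over the tiles that all 6 libraries cover (413 over those that the other 4 cover), so the share of the count that this library gives is open. The same direction was found in 71.5% between the antigens in the day 8 tumour (random tiles 48.1% to 52.7%) and in 59.8% at day 12 (50.1% to 54.7%). An antigen difference shared by other cells would give this, although at day 8 the share was 76.8% for tiles lower and 55.6% for tiles higher under M9. The shares were not repeated without the shallow C6M9 replicate 2 and C6M9 TIM3neg libraries. At day 8 an antigen difference thus cannot be told from a trait that these shallow C6M9 libraries share. A shift of M9 lymph node cells toward the TIM3pos state was not settled, since the share of 62.9% lay above that of random tiles (54.3% to 58.6%) by less than the margin set beforehand.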

How the results depend on the processing

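Among 217 named regions, 2822 of 3537 values under other settings kept their direction and side of the threshold, 692 were no longer called, 20 became called and 3 turned direction. The turns all came at a minimum of 10 reads, at the gene ends of 1700011L22Rik (-1.08) and Des (2.55) between antigens in the tumour, and of Prf1 between TIM3neg tumour and lymph node cells (10.1, adjusted p = 0.0311). Of called named regions, 251 of 407 values held between the lymph node groups, 309 of 504 between TIM3pos and TIM3neg, 211 of 480 between antigens in the tumour and 702 of 776 between TIM3neg tumour and lymph node cells. Only the last comparison had regions called under every setting, 18 of 42. Over all counts, 168 values stayed within 1.5 times or within the spread, while others moved further, as the counts below show. The 3 settings with read weights, without both lymph node replicate 2 libraries and without the 2 shallowest libraries were added after the data were seen. The cause of each change below was not tested, except that a larger or no minimum difference and fewer CpGs at 10 reads change the counts by construction. Depth limits the tiles, since only 68.1% of CpGs reach the 5 read minimum in the shallowest library. Limma without read weights recovered 0% of simulated tiles in the lymph node and both day 8 tumour comparisons. Its counts of 0 tiles there cannot test the calls.

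Between the lymph node groups 1817 tiles became 471 at 20 points, 0 with limma, 230 with read weights, 112 at 10 reads, 845 in 2 kb tiles and 413 without both replicate 2 libraries. Leaving out each library gave 960 to 2110 tiles, 0 to 1 gene ends and 0 to 0 gene bodies. With the replicate block 33 tiles were called. Same-numbered libraries correlated by 0.0365, 0.00554 and 0.0151 against -0.0310 to 0.0123 for others. Every library except C6M9 replicate 2, the shallowest, correlated best with its own number. The levels thus lean towards pairing by number without settling it, and the 1817 tiles called without a block may ignore a pairing. Chromosome X coverage relative to the autosomes also sets replicate 2 of both antigens apart (0.825 and 0.874, against 0.460 to 0.503 in the other day 8 libraries). Chromosome Y coverage was lower there (0.0270 and 0.0423, against 0.169 to 0.225). More X with less Y is what another sex would give, with or without another batch, and no label gives either. The tumour comparisons use single libraries per group and share no replicate numbers. Mean squared differences between lymph node libraries were 1.26 to 1.36 times the sampling variance in all 15 pairs, so none is a copy of another. The lowest was that of M9 replicate 1 and C6M9 replicate 1, across antigens. The highest was that of M9 replicate 2 and C6M9 replicate 2, which also share a number.

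Between TIM3pos and TIM3neg, 1634 tiles became 614 at 20 points, 2626 with no minimum difference, 0 with limma, 471 with read weights, 26 at 10 reads and 0 with the spread of the 4 tumour libraries only. The 32 ends became 4, 191, 1, 8, 0 and 0 in the same order, 10 with chromosome X, 12 in the longer windows (3 kb instead of 1.5 kb) and 2 without the 2 shallowest libraries. The 12 bodies became 1 at 20 points, 436 with no minimum difference, 0 with limma, 6 with read weights and 4 at 10 reads. Leaving out each library gave 1790 to 2029 tiles, 2 to 149 ends and 0 to 0 bodies. Between antigens in the tumour, 877 tiles became 151 at 20 points, 2261 with no minimum difference, 0 with limma, 76 with read weights, 65 at 10 reads, 0 with the spread of the 4 tumour libraries only and 517 without the 2 shallowest libraries. The 49 ends became 1, 371, 0, 15, 14, 0 and 12 in the same order, 24 with chromosome X and 16 in the longer windows. Leaving out each library gave 662 to 2841 tiles, 21 to 201 ends and 0 to 0 bodies. A library that is left out leaves a pair whose spread is assumed to be that of the other groups.

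Between TIM3neg tumour and lymph node cells, 87097 tiles became 16164 at 20 points, 1059 with limma, 40179 with read weights, 2508 at 10 reads, 137343 at 1 read, 51248 in 500 base tiles, 15813 with only replicate 1 lymph node libraries and 26592 without the 2 shallowest libraries. The 645 ends became 52 at 20 points, 2650 with no minimum difference, 186 at 10 reads, 261 with only replicate 1 and 175 without the 2 shallowest. The 242 bodies became 16 at 20 points, 4303 with no minimum difference, 402 with limma, 115 with only replicate 1 and 55 without the 2 shallowest. Leaving out each library gave 19870 to 114784 tiles, 167 to 1153 ends and 43 to 756 bodies. The global difference of -3.10 points became -2.25 at 10 reads.

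In single libraries, day 12 tiles (59) became 81342 when thinned to 20 observations, 6 at 40 points and 6 at 10 reads, and ends (0) 672 when thinned. Between antigens in TIM3neg the tiles became 73558, 533 and 2072 and the ends 648 (thinned) and 3 (40 points). In TIM3pos they became 69673, 45 and 599, with ends 536, 1 and 1. Between TIM3pos and TIM3neg under M9 the tiles became 68489 (thinned) and 58 (40 points), with ends 563, 1 and 5, and under C6M9 the tiles 72768, 421 and 1743, with ends 651, 1 and 9. Gene lists called by camera fell to 0 with an estimated correlation in all comparisons, from 1 (ends) and 2 (bodies) in the lymph node, 1 and 2 for TIM3, 3 and 2 between antigens in the tumour, and 2 and 3 for TIM3neg tumour against lymph node.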

Other observations

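Lymph node tiles of both directions kept their direction between the antigens in the tumour beyond random tiles matched on level. Of tiles lower under M9, 76.8% were lower in the day 8 tumour too, with a median difference of -4.15 points there (random -0.598 to 0.190), and of tiles higher under M9 55.6% were higher, with a median of 0.708 points (random -1.06 to 0.297). At day 12 the shares were 59.4% (lower, median -1.08 points, random -0.680 to -0.174) and 61.1% (higher, median 0.989 points, random -0.770 to 0.176). These shares were not repeated without the shallowest C6M9 libraries of the lymph node and the day 8 tumour.

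Over the CpGs covered in all 10 day 8 libraries, bodies of 3 cytotoxic genes were lower in TIM3pos cells under each antigen in single libraries. The Ifng body was not called with the 4 tumour libraries together. The Gzmb body was lower in TIM3pos than TIM3neg cells by -31.8 points under M9 and -33.5 under C6M9, the Prf1 body by -18.5 and -11.45 points, the Ifng body by -17.4 and -10.5 points, and the Tcf7 body higher by 7.11 and 6.64 points.

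Coverage of chromosome X relative to the autosomes was 0.825 and 0.874 in lymph node replicate 2 of M9 and C6M9, 0.460 to 0.503 in the other day 8 libraries, and 0.726 and 0.748 in the day 12 libraries. Coverage of chromosome Y was 0.0270 and 0.0423 in lymph node replicate 2 and 0.169 to 0.225 in the other day 8 libraries. Isolated CpGs lost 4.19 (M9) and 3.81 (C6M9) points more than CpGs with 1 or 2 neighbours at day 12, 1.75 and 2.50 in TIM3neg, and 2.69 and 2.89 in TIM3pos libraries.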
